A study of Mus musculus with 2 samples.

How the data were processed

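Expression was measured on 2 Affymetrix mouse whole-genome arrays, 1 for naive CD8+ T cells and 1 for CD8+ T cells 72 h after activation. Cells were purified from pmel-1 T cell receptor transgenic mice, per the series' design text, and the purification method and the source organ are not given in the sources used here. RNA was purified with a column kit and pooled from 4 independent experiments per array, per the labels' protocols, so that the spread between experiments cannot be seen.

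The authors deposited 1 model-based expression intensity per probe set on a linear scale. Per the design text, the submitters computed these values with the difference model of dChip, which subtracts mismatch from perfect-match probes, and normalized the arrays with its invariant set method. The dChip version is not given in the sources used here. Present and absent calls were made with GCOS 1.3, per the submitters' processing notes and the design text, and these calls were not used here. The design text also states the study's rule for a difference, which combines a present call, a lower confidence bound of the fold above 1.4 and a difference above 100. Confidence bounds and calls were not used here, so the rule applied below keeps only the parts that the intensities allow. It is looser than the study's in that respect. Near background it can be stricter, because values under 100 were raised to 100 before the ratio was formed. Difference-model values near background carry little information, and the lowest deposited intensity was 1, held by 1545 probe sets of the naive array and 1674 of the activated array.

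The table held 45101 probe sets, of which 64 controls were left out of all counts. Gene symbols came from the platform's annotation, in which 34945 of the remaining probe sets had 1 symbol, 932 had several and 9160 were unnamed here. Entrez identifiers of 34741 probe sets matched the RefSeq gene table of mouse assembly GRCm38.p6, which changed 0 symbols and was used for names only, and no coordinates are given because no build is named with the values. Probe sets with several symbols named no gene. Of the probe sets past the size rule, 7174 had 1 symbol, 205 several and 552 none.

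A probe set passed the size rule when the ratio of the arrays, with values under 100 raised to 100, was at least 1.4 and the deposited values differed by more than 100. Where 1 value lay under 100 the fold is a lower bound, and where both did no ratio was formed, so that a gene counts as measured when at least 1 of its values reached 100. Each of 18193 genes was represented by its probe set with the highest mean over both arrays. For each gene list the median log2 ratio of its measured members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. The percentile describes these 2 arrays and is not a test. Before the data were examined, 26 gene lists and 9 lists of markers of other cell types were fixed, together with the rule for named genes. That rule names every salvage kinase, nucleoside breakdown and transporter gene, the 10 highest and 10 lowest ratios among genes reaching 500, and in each other list up to 4 members with the largest ratios past the size rule and up to 2 nearest to 0. It also names the CD8 and T cell receptor genes and reference genes, and up to 4 markers past the size rule per other cell type. Genes named outside this rule, such as Rrm2b, Prps2, Impdh1, Aprt and Atm, were chosen after their values were seen. List members without a probe set of their own symbol were not analysed here, 8 of 87 in the union of the 7 nucleotide lists.

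The procedure was tested on simulated data for 18193 genes at the mean levels of the 2 arrays and a log2 spread of 0.2. All 100 genes changed 2-fold and all 100 changed 4-fold were recovered, and 91 of 17993 unchanged genes passed the size rule. The changed genes were drawn from brighter genes only, so recovery near the floor of 100 was not tested. Only 9848 of the 18193 genes were measured on the real arrays, so the unchanged genes include many that could hardly pass. The simulated spread also lay below the 0.39 found between probe sets of the same gene. The 91 therefore gives no rate of false calls for measured genes. Of 100 random lists with no change, 6 fell outside the middle 95%, and all 20 lists with raised genes lay above that range. As checks on the arrays, 18 spike-in probe sets above 100 gave log2 ratios from -0.42 to 0.20 with a standard deviation of 0.19. The signal ratio of 3' to 5' probe sets, a sign of RNA integrity, was 1.20 and 1.11 for Actb and 0.85 and 0.86 for Gapdh on the naive and activated arrays. Across probe sets above 100 on both arrays the median log2 ratio was 0.01 and the Pearson correlation of log2 values 0.85, a correlation across probe sets, which are not independent replicates.

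Alternatives were a fold minimum of 2, a difference minimum of 50 or 200, a floor of 50 or 200, median, quantile and loess scaling in place of the deposited one, the mean over a gene's probe sets, counting genes, and leaving out probe sets whose names mark possible cross-hybridization. A fold minimum raised by the spread between probe sets, and a rule requiring both values to reach 100, were added after seeing the data. Loess used a span of 0.3. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.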

Results

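Gene expression was compared between naive and activated CD8+ T cells of pmel-1 mice, a strain carrying a transgenic T cell receptor against a melanocyte antigen. Total RNA was taken from purified naive cells and from proliferating cells 72 h after activation. Each of the 2 RNA pools combined 4 independent experiments and was hybridised to 1 whole-genome mouse array, so neither group had replicates. No difference below has a replicate error, a test or a p-value, and the number of arrays limits the precision of every value. The arrays carried 45037 probe sets other than controls. Deposited intensities had a median of 56.2 on the naive array and 52.3 on the activated array, with maxima of 14412 and 15050.4. At 25787 probe sets (57.3%) both values lay under 100, the level below which values were not compared. The study's title names positron emission tomography of lymphoid organs with a labelled deoxycytidine analogue, and its design text singles out nucleoside salvage, synthesis and transport genes. The comparison therefore addressed how these genes, and the programme of activation around them, differed between resting and proliferating CD8+ T cells.

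Among genes reaching 500 on either array, chemokine, cytotoxic, metallothionein and mitotic genes were among the 10 highest ratios of activated over naive cells. Ccl3, an inflammatory chemokine, had the highest ratio among genes reaching 500 on either array, at 29.8 on the naive array and 5768 on the activated array (at least 57.7-fold higher). Gzmb, the cytotoxic protease granzyme B, was at 282 and 10896 (38.6-fold higher), and Ifng, encoding interferon gamma, was at least 32.8-fold higher. The other highest ratios belonged to Nrn1 (at least 44.8-fold), the metallothioneins Mt1 (25.5-fold) and Mt2 (at least 24.3-fold), the chemokine Ccl4 (at least 25.1-fold), the mitotic genes Ube2c (23.0-fold) and Cdk1 (21.4-fold), and Cd200 (at least 20.7-fold). In the other direction, Ccr9, a chemokine receptor for homing to the gut, was at 4421 and 13.3 (at least 44.2-fold lower), although its other probe sets above 100 gave smaller log2 differences, down to -0.38. Itgae, the integrin CD103, was at least 26.6-fold lower, Ifit1bl1 23.2-fold, the actin-bundling gene Fscn1 at least 21.3-fold, Mylip at least 19.1-fold and Tdrp at least 17.0-fold. Genes of other blood cells stood among the 10 lowest ratios as well, namely Hbb-b2 (at least 68.5-fold lower), Igkv8-30 (at least 25.04-fold), H2-Aa (at least 20.1-fold) and Jchain (at least 17.7-fold). Other probe sets above 100 gave smaller log2 differences, down to -0.62 for Fscn1, -0.18 for Hbb-b2 and -0.03 for H2-Aa. Such values are lower bounds of the difference where 1 array lay under 100. Hbb-b2 encodes beta-globin and has near-identical neighbours, so its value is uncertain as to the gene, and Igkv8-30 and Jchain belong to immunoglobulins. By the size rule, 4224 probe sets were higher and 3707 lower in activated cells, at least 1.4-fold and by more than 100. Of these, 501 higher and 282 lower probe sets differed at least 4-fold, and 751 and 670 had the other array under 100, so that their fold is a lower bound. Counted by gene, 2334 of 9848 measured genes were higher and 2027 lower. Probe sets of the same gene differed in log2 ratio with a standard deviation of 0.39, and 56 of 4873 genes were called both higher and lower by different probe sets. Among genes past the size rule named below, another probe set above 100 had the opposite sign for Adk, Brca1, Ccr2, Cdc45, Dnajc3, Gmps, Il18rap, Prps2, Rad54l and Tubb5. With a fold minimum of 2 in place of 1.4, 2121 probe sets were higher and 1750 lower.

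**Figure D1:**
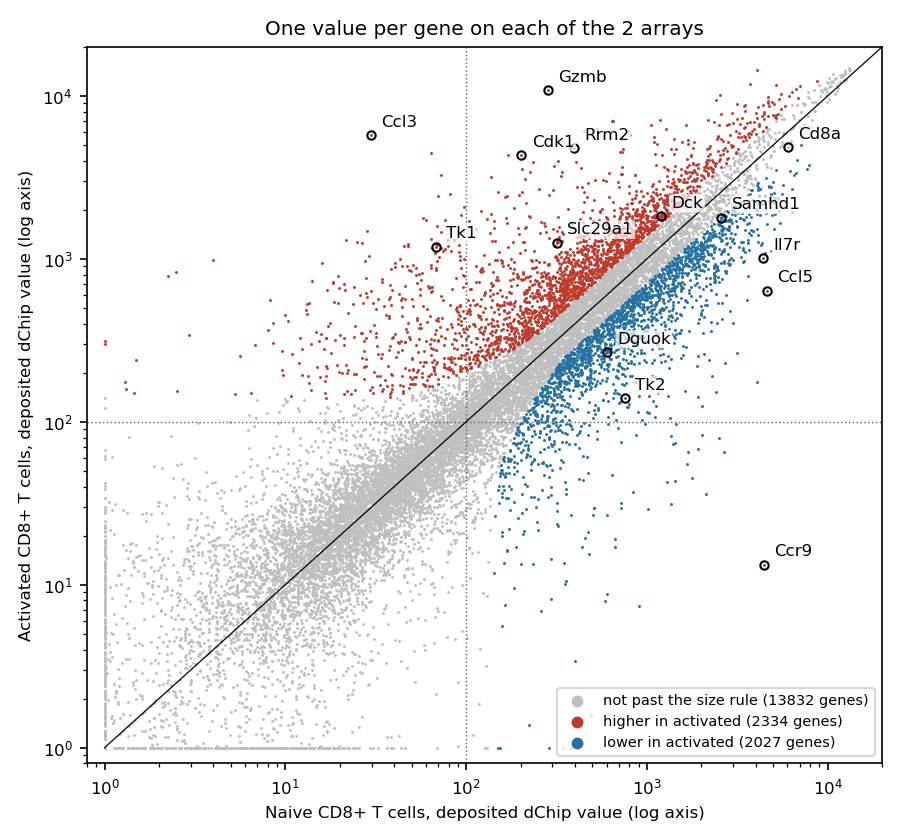
Each point is 1 gene, with its deposited value on the naive array on the x axis and on the activated array on the y axis, both in intensity on log axes; red and blue points pass the size rule, dotted lines mark 100 and the diagonal marks equal values. Gzmb lies at 282 and 10896, Ccr9 at 4421 and 13.3, and Dck, at 1200.0 and 1833, lies close to the diagonal.

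The deoxyribonucleoside salvage kinases, which add the first phosphate to deoxynucleosides, divided by cellular compartment under the 1.4-fold size rule. Both cytosolic kinases were higher in activated cells and both mitochondrial kinases were lower. The split is limited, since Dck did not reach a fold minimum of 2 by its brightest probe set. Tk1, Tk2 and Dguok rested on 1 probe set each. Dck, deoxycytidine kinase, was already at 1200.0 in naive cells and at 1833 in activated cells (1.53-fold higher). Its 3 probe sets gave log2 ratios of 0.39, 0.61 and 1.42, and the first of them did not pass the size rule. Tk1, the S-phase thymidine kinase, was at 68.0 and 1189 (at least 11.9-fold higher). Tk2 was at 753 and 140.1 (5.37-fold lower), and Dguok, deoxyguanosine kinase, at 599 and 268 (2.24-fold lower). With members on both sides of 0, the median log2 ratio of the 4 kinases was -0.28, at percentile 26.98 of random gene lists matched on mean expression.

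Among the nucleoside transporters, which carry nucleosides across membranes, Slc29a1, the equilibrative transporter ENT1, was the only one of 4 measured members past the size rule. Slc29a1 was at 316 in naive and 1258 in activated cells (3.98-fold higher). Slc29a3 was at 391.6 and 472, Slc29a4 at 305 and 272, and Slc29a2 at 112 and 80.5. The concentrative transporter Slc28a3 lay under 100 on both arrays (22.1 and 31.4), and Slc28a1 and Slc28a2 were not analysed here. The list median was 0.05 (percentile 57.29).

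Enzymes that break down nucleosides and deoxynucleotides went both ways, with 5 of 13 measured members higher and 2 lower. Cda, cytidine deaminase, which inactivates deoxycytidine and many of its analogues, lay under 100 on both arrays (17.2 and 1). Higher members were Xdh (3.22-fold), the purine nucleoside phosphorylase Pnp (2.19-fold), the deoxycytidylate deaminase Dctd (2.04-fold), Nt5c2 (1.98-fold) and Dera (1.85-fold). The ecto-nucleotidase Nt5e (CD73) was at 381 and 119 (3.20-fold lower). Samhd1, a deoxynucleotide triphosphohydrolase, was at 2580.2 and 1792 (1.44-fold lower), and 2 of its 5 probe sets above 100 did not pass the size rule. Members that did not pass were Nt5c (1379.5 and 1422), Nt5m (182 and 215), Nt5c3 (703 and 663), Nt5c3b (459.5 and 568), Ada (205 and 154) and Gda (74.6 and 106). Upp1, Upp2, Dpyd, Dpys, Upb1, Uox and Nt5c1b lay under 100 on both arrays, as did Cda. The median was 0.24 (percentile 86.47).

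Salvage of ribonucleosides and bases was higher for 5 of 9 measured genes and lower for 2. Adk, adenosine kinase, was 3.68-fold higher by its brightest probe set, although its 3 probe sets ranged from -0.14 to 2.03 on the log2 scale. Uck2, a uridine-cytidine kinase, was 3.11-fold higher, and the purine base salvage enzymes Hprt and Aprt were 1.78-fold and 1.45-fold higher. Ampd3 (at least 2.22-fold) and Uckl1 (1.95-fold) were lower, and Uck1 was at 444 and 431. The median of 0.50 lay at percentile 95.56, inside the middle 95% of random lists.

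De novo pyrimidine synthesis was higher for 3 of 5 genes, with a median log2 ratio of 1.31 at percentile 99.69. Cad, whose product starts the pathway, was 2.49-fold higher, Umps, which ends it with uridine monophosphate, 2.83-fold, and the CTP synthase Ctps 2.78-fold. Dhodh (310.1 and 372) and Ctps2 (1428 and 1129.6) did not pass the size rule. In de novo purine synthesis 7 of 13 measured genes were higher and 2 lower. Pfas was 3.49-fold higher, Gmps 2.55-fold, Ppat, the committed step, 2.42-fold, and Paics 2.12-fold, while Prps2 (1.69-fold) and Impdh1 (1.57-fold) were lower. The probe sets of Gmps ranged from -0.23 to 1.35, and Impdh2 was not analysed here. Prps1l3 was at 1211 and 1288. The purine median of 0.50 lay at percentile 96.61, inside the middle 95%.

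The deoxyribonucleotide production list, which holds ribonucleotide reduction, folate and nucleotide kinase genes, was higher for 14 of 19 measured genes and lower for 1. Of the higher members, Dctpp1 (3.97-fold), Nudt1 (2.82-fold) and Itpa (2.66-fold) encode enzymes that hydrolyse nucleotides, and were named after their values were seen. Rrm2 and Rrm1, the subunits of S-phase ribonucleotide reductase, were at 396 and 4801 (12.1-fold higher) and at 433 and 3598 (8.31-fold higher). Rrm2b, the subunit used outside S phase, was at 551 and 174 (3.17-fold lower), the only lower member. Dut, which removes dUTP, was 5.74-fold higher and the folate enzyme Shmt1 5.67-fold. Cmpk1 (2224 and 2086) and Cmpk2 (373 and 352) lay nearest to no difference. Tyms lay under 100 on both arrays by the probe sets that name it alone (18.4 and 97.4 for the brightest), while a probe set that Tyms shares with its pseudogene Tyms-ps was at 81.9 and 1117.5 (log2 ratio of at least 3.48). The median was 1.06 (percentile 100). Over the union of the 7 nucleotide lists, 37 of 67 measured genes were higher and 9 lower, with a median log2 ratio of 0.55 at percentile 100. Without the deoxyribonucleotide production genes the median of the other 48 was 0.44, at percentile 99.97.

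**Figure D2:**
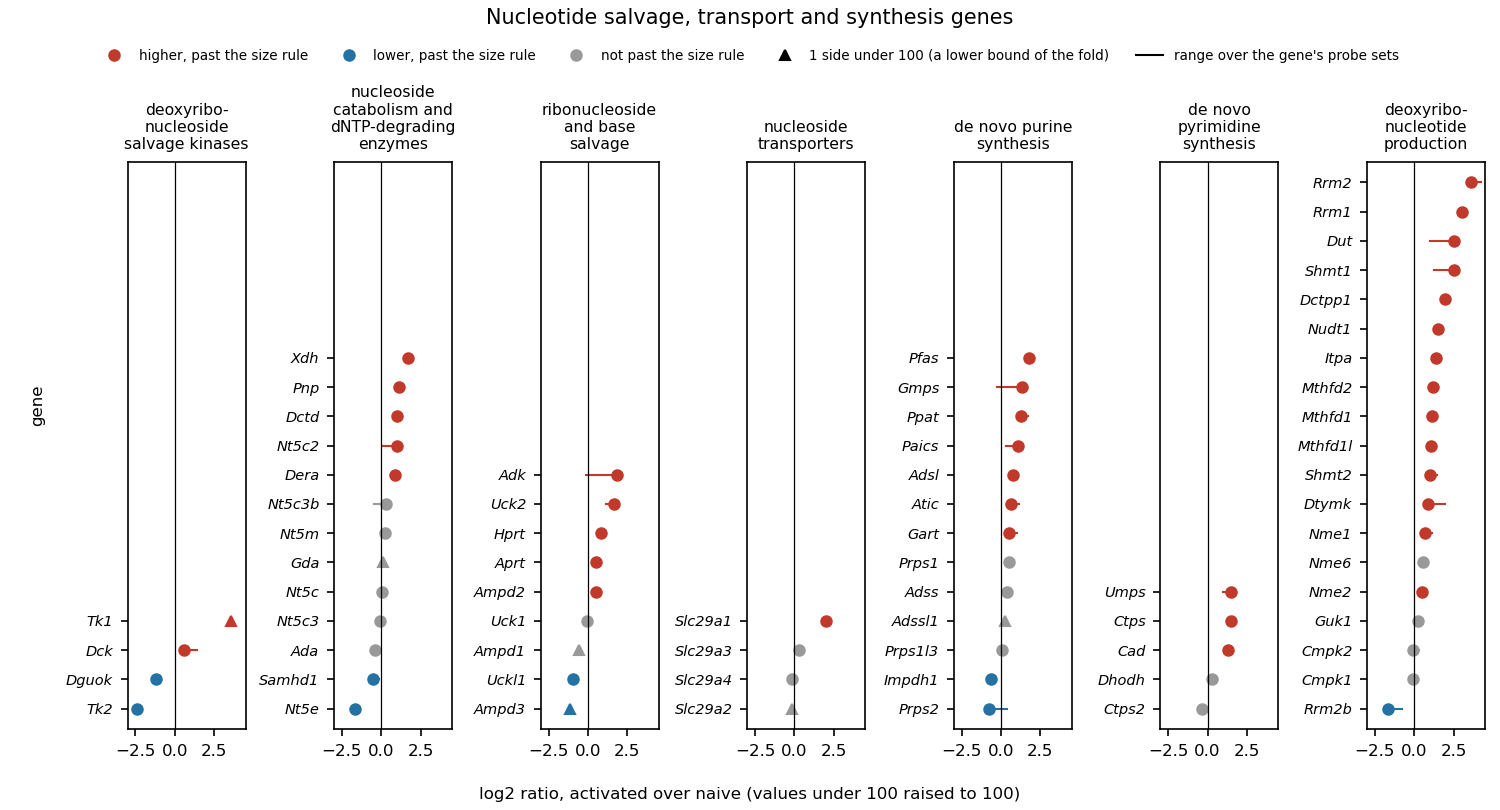
Log2 ratio of activated over naive cells (x axis) for the measured genes (y axis) of 7 nucleotide lists, with points for the brightest probe set, triangles where 1 array lay under 100, and lines for the range over a gene's probe sets; red is higher and blue lower past the size rule. Tk1 (3.57) and Dck (0.61) lie on the right and Dguok (-1.16) and Tk2 (-2.43) on the left of the kinase panel, and Rrm2 (3.60) and Rrm2b (-1.67) at opposite ends of the deoxyribonucleotide panel.

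Genes of DNA replication and of mitosis had higher median ratios than every nucleotide list. Of 40 DNA replication genes, 39 were higher, with a median log2 ratio of 1.69 (percentile 100). Cdc6, which loads the replicative helicase, was at least 13.2-fold higher, Top2a, which untangles DNA, 12.3-fold, Cdc45 at least 8.57-fold and Gins1 at least 8.41-fold. Rpa1, at 3366 and 4059, was the exception, and Cdt1 was 1.59-fold higher. Of 41 measured mitosis and cell cycle genes, 37 were higher and none lower by the size rule, with a median of 3.14 (percentile 100). Besides Ube2c and Cdk1, Birc5 (survivin) was 17.1-fold higher and Nuf2, a kinetochore gene, at least 15.2-fold, while Ccnd2 was at 2809 and 3180.5 and Kif23 at 901 and 988. DNA damage and repair genes were higher for 11 of 16 and lower for 1, with a median of 1.26 (percentile 100). Chek1, a replication checkpoint kinase, was at least 9.71-fold higher, Exo1 at least 6.598-fold, Rad54l at least 5.80-fold and Brca1 at least 5.57-fold. The lowest log2 ratio among the probe sets above 100 was 0.37 for Chek1, -0.48 for Rad54l and -0.38 for Brca1, and -0.33 for Cdc45 above. Atr (709 and 739) and Bbc3 (185 and 168) did not pass, and the damage kinase gene Atm was 1.649-fold lower.

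Quiescence genes and cell cycle inhibitors were lower for 10 of 17 members and higher for 2, with a median of -0.87 (percentile 0.01). Tsc22d3, a glucocorticoid-induced gene, was 6.24-fold lower, the transcription factor Foxo1 3.04-fold and the antiproliferative gene Btg2 2.83-fold. Cdkn1a, the inhibitor p21, went the other way at 62.4 and 660.0 (at least 6.6-fold higher). Tob1 (709.5 and 725) and Ddit4 (1689 and 1881) did not pass. Genes of naive T cells were lower for 13 of 16 measured members, with a median of -1.40 (percentile 0). Igfbp4 was 7.49-fold lower, S1pr1, the receptor for leaving lymph nodes, 6.28-fold, the cytokine receptor subunit Il6st 6.09-fold and the kinase gene Txk 5.46-fold. Bach2 (1092 and 1184) and Bcl2 (2509 and 2236) did not pass, and Tcf7 and Ly6c1 were not analysed here.

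Effector genes were higher for 15 of 23 measured members and lower for 3, with a median of 0.78 (percentile 100). Ccl3, Gzmb, Ifng and Ccl4 led the list, as given above, while Nkg7 (3952 and 4059.5) and Xcl1 (825 and 982) did not pass. The 3 lower members, named after their values were seen, were the chemokine Ccl5 (4619 and 638, 7.24-fold), the granzyme Gzma (989 and 232, 4.27-fold) and the cytokine Ltb (6337 and 1929, 3.29-fold). Activation and co-stimulation receptors were higher for 15 of 22 measured members and lower for 5, with a median of 1.01 (percentile 100). Pdcd1 (PD-1) was at least 16.0-fold higher, Ctla4 15.03-fold, the interleukin-2 receptor chain Il2ra at least 14.9-fold and Tnfrsf9 (4-1BB) 11.04-fold. Cd69, an early activation marker, was at 1049.8 and 860.1, and Cd160 at 389.6 and 522, neither past the size rule. The 5 lower receptors, named after their values were seen, were Cxcr6 (4.60-fold), Ccr2 (2.13-fold), Il18r1 (1.52-fold), Cxcr3 (1.52-fold) and Il18rap (1.42-fold). Of 27 transcription factors, 11 were higher and 7 lower, with a median of 0.27 (percentile 92.28). Bhlhe40 was at least 17.3-fold higher, Irf4 at least 14.7-fold, Batf3 at least 9.87-fold and Nr4a3 9.30-fold, while Runx3 (1095 and 1076) and Stat4 (1870.5 and 1763) did not pass.

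Transcripts that define the CD8 T cell were abundant on both arrays, with 7 of 14 lower and none higher by the size rule. Cd8a was at 6020.4 and 4860.0, Cd3d at 7378 and 6597, Cd3e at 3035 and 2724, Cd3g at 6261 and 5323, and Zap70 at 1524 and 1171, none of them past the size rule by the brightest probe set, although the 5 probe sets of Cd8a above 100 ranged from -1.39 to -0.31 on the log2 scale. Cd5 (1138 and 1184) and the adaptor gene Lcp2 (1938 and 2216) did not pass either. The lower members were the adaptor gene Fyb (3.25-fold), Cd8b1 (2.17-fold), Lat (1.84-fold), Thy1 (1.73-fold), Cd2 (1.58-fold), Cd247 (1.53-fold) and Cd6 (1.45-fold). The list median was -0.46 (percentile 0.45). Of 9 reference genes often used for scaling, 4 were higher, namely Gusb (2.30-fold), Tubb5 (2.08-fold), Hprt (1.78-fold) and Tbp (1.51-fold). Actb (10647 and 12280.0), B2m (10479 and 11471), Ywhaz (4196 and 5060.2), Rpl13a (13275 and 14517) and Sdha (2369.7 and 2211) did not pass. Their median was 0.27 (percentile 66.12).

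Among biosynthetic and energy genes outside the nucleotide lists, cholesterol synthesis differed most, followed by glycolysis and amino acid supply. Of 18 measured cholesterol synthesis genes, 17 were higher, with a median of 2.56 (percentile 100). Cyp51 was 17.3-fold higher, Idi1 16.8-fold, the oxidative step Sqle 13.9-fold and Hmgcs1 10.8-fold, although 1 probe set of Hmgcs1 gave only 0.15 on the log2 scale. Srebf2, the regulator of the pathway, was 1.44-fold higher and Mvk, at 114 and 178, did not pass. Glycolysis and lactate export genes were higher for 14 of 18, with a median of 1.47 (percentile 100). Hk2, a hexokinase, was at least 12.1-fold higher, Tpi1 10.9-fold, the lactate exporter Slc16a3 at least 5.76-fold and Aldoc at least 5.67-fold, while Hk1 (1448 and 1476) and Pfkfb3 (366 and 354) did not pass. In the pentose phosphate pathway, the source of ribose for nucleotides, 2 of 7 were higher, Tkt (2.52-fold) and Pgd (2.44-fold), with a median of 0.25 (percentile 73.75). Rpe (843 and 891) and Taldo1 (1523 and 1392) did not pass. Amino acid transport and one-carbon genes were higher for 11 of 14, with a median of 1.12 (percentile 100). Asns, asparagine synthetase, was at least 10.4-fold higher, the serine synthesis genes Psat1 and Phgdh 5.49-fold and 3.11-fold, and the leucine transporter Slc7a5 4.19-fold, while Glud1 (1586 and 1654) and Slc38a2 (2085 and 1919.6) did not pass. Respiratory chain genes were higher for 15 of 31, with a smaller median of 0.47 (percentile 98.94). Cycs, cytochrome c, was 2.33-fold higher, Sdhd 2.19-fold, Cox5b 2.17-fold and Uqcrfs1 1.95-fold, while Ndufa1 (3717 and 3728) did not pass. Ribosome biogenesis genes were higher for 22 of 25, with a median of 0.82 (percentile 100). Nhp2 was 2.69-fold higher, Nolc1 2.43-fold, Wdr12 2.28-fold and Gar1 2.09-fold, while Polr1a (380.3 and 504) and Fbl (3266 and 4343) did not pass. None of 19 measured cytosolic ribosomal protein genes passed the size rule, as with Rps24 (12443 and 12579) and Rps14 (11348 and 11212). Their median of 0.14 (percentile 29.91) turned to -0.02 with quantile normalization and to -0.13 with loess, so no direction is given.

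**Figure D3:**
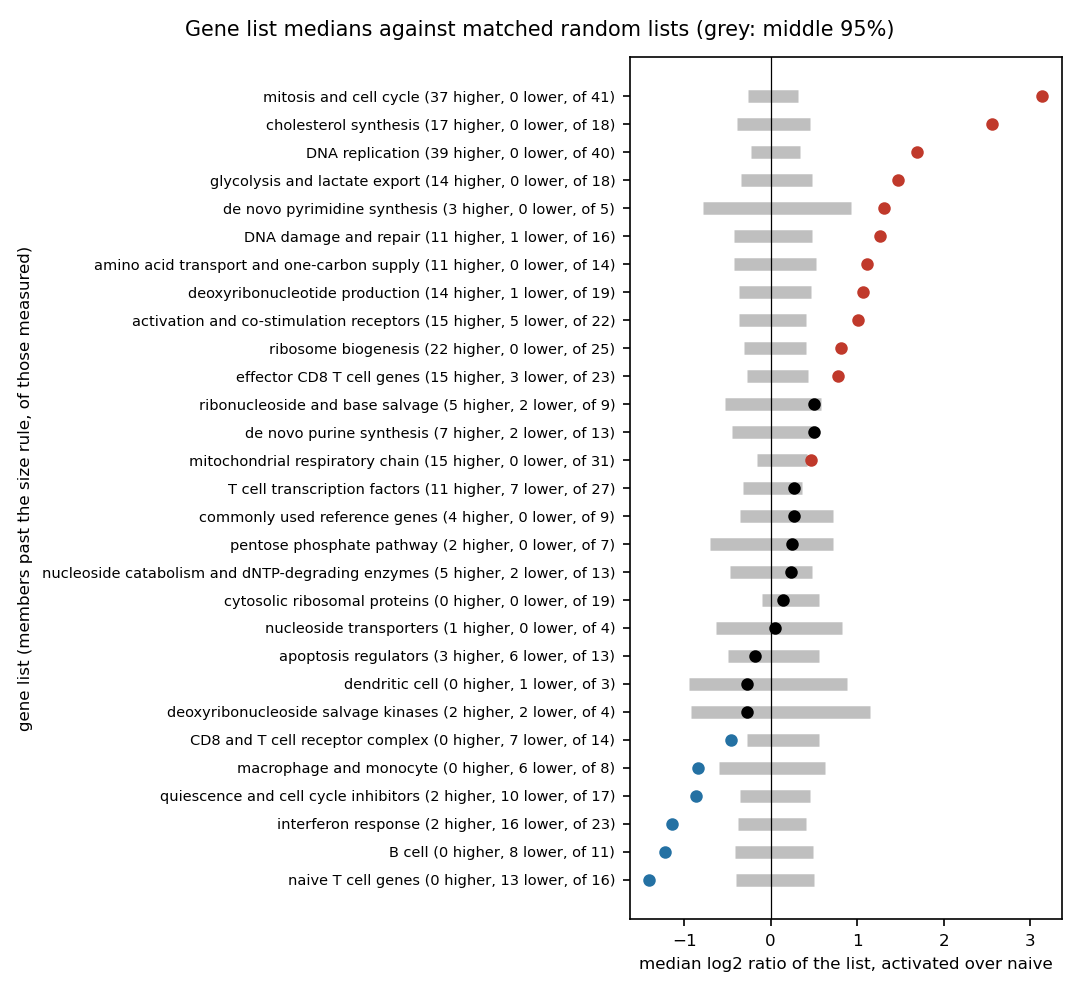
Median log2 ratio of activated over naive cells (x axis, points) for each gene list with at least 3 measured members (y axis), beside the middle 95% of 10000 matched random lists (grey bars); red and blue points lie above and below that range. Mitosis and cell cycle genes (3.14) stand highest and naive T cell genes (-1.40) lowest.

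Interferon response genes were lower in activated cells for 16 of 23 measured members and higher for 2, with a median of -1.15 (percentile 0). Usp18, which dampens interferon signalling, was at 975 and 97.49 (at least 9.75-fold lower), Ifit3 at 1032 and 113 (9.13-fold), Ifit1 at least 7.19-fold lower and the transcription factor Irf7 4.19-fold. Ifih1 (1.46-fold) and Gbp3 (1.44-fold), named after their values were seen, were the 2 higher members, and Oas3 (157 and 143) and Gbp2 (2164 and 2420.5) did not pass. Apoptosis regulators were split, with 3 of 13 higher, 6 lower and a median of -0.18 (percentile 19.3). This median was -0.34 with quantile normalization or loess, and lower still with the mean over probe sets. The survival gene Bcl2l1 was 3-fold higher, and the death genes Bak1 and Pmaip1 were 2.74-fold and 2.62-fold higher. The death receptor gene Fas was 2.67-fold lower, and Mcl1 (3599 and 3239) did not pass.

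Among markers of other cell types, those lower on the activated array came mostly from the B cell and the macrophage lists. B cell and antigen-presentation markers were lower for 8 of 11 measured members, with a median of -1.22 (percentile 0). H2-Aa and H2-Eb1, class II genes, were at least 20.1-fold and at least 13.9-fold lower, their chaperone Cd74 was at 3003 and 405 (7.41-fold lower) and the kappa chain gene Igk was at least 3.43-fold lower. The 4 probe sets of H2-Aa above 100 ranged from -4.33 to -0.03 on the log2 scale. Cd79b was at least 2.93-fold lower, and Cd79a (112 on the naive array) and Ms4a1 (136) did not pass. Ighm, also a list member, was at -0.75 on the log2 scale by its brightest probe set and as low as -4.71, a lower bound of the difference, among its 7 above 100. Outside the list, 3 probe sets shared by Igkc and kappa variable genes had log2 ratios of -5.21, -4.63 and -4.45. Macrophage and monocyte markers were lower for 6 of 8 measured members, with a median of -0.84 (percentile 0.29). Lyz1 was at least 3.54-fold lower, Mpeg1 at least 2.93-fold, Tyrobp at least 2.60-fold and Csf1r 1.86-fold, while 9 others lay under 100 on both arrays. Of 3 measured dendritic cell markers, Ccl22 was at least 2.84-fold lower, with a list median of -0.27 (percentile 15.94). Of 2 measured NK cell markers, the activating receptor Klrk1, which CD8 T cells also express, was 5.11-fold higher and Klra8 at least 2.42-fold lower. Pecam1, the 1 measured stromal and endothelial marker, was 2.54-fold lower. None of the measured neutrophil (1), erythroid (2), platelet (2) or CD4 and regulatory T cell (2) markers passed the size rule, and Cd4 itself lay at 45.1 and 50.5. The 2 measured erythroid markers do not include globin, whose brightest probe sets name several genes and were far lower on the activated array, as with alpha-globin (8254 and 25.4) and beta-globin (7395 and 22.5).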

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

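No explanation was tested for the values in this part, which come from control probe sets left out of all counts above. Of the 64 controls, 7 passed the size rule, each higher on the activated array. The 3 controls for Gapdh, a glycolytic enzyme often used for scaling, had log2 ratios of 1.29 at the 3' end (4642 and 11333), 1.27 at the 5' end (5454 and 13192) and 1.52 in the middle (4376 and 12552). The 3 controls for the transferrin receptor, which imports iron, had log2 ratios of at least 3.63 at the 3' end (91.7 and 1240.3), 2.46 at the 5' end (19.5 and 552) and 2.49 in the middle (18.1 and 563), all lower bounds because the naive value lay under 100. Outside the controls, the transferrin receptor gene Tfrc was 7.70-fold higher. The murine b1 control had a log2 ratio of 1.44 (1817 and 4944). The 18 spike-in probe sets above 100 lay between -0.42 and 0.20.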

How the results depend on the processing

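The fold minimum raised by the spread between probe sets and the rule requiring both values to reach 100 were chosen after the data were seen. Among genes past the size rule, none named by the fixed rule and no member of the 12 later lists turned its direction under any alternative. Other genes named in the text, such as Prps2 and Rrm2b, were not examined in this way. Of the list medians only that of the ribosomal proteins, in which no gene passed the size rule, changed sign. The causes of the shifts below were not tested. Among counts, 17 alternative values stayed within 1.5 times the reported one and 7 did not. The 4224 higher and 3707 lower probe sets became 2121 and 1750 with a fold minimum of 2, 2334 and 2027 when genes were counted, and 1715 and 1363 with the fold minimum raised to 2.18, and the lower ones became 2454 with a difference minimum of 200. The share of higher calls was 53.3% as reported and 49.5% to 56.8% over the alternatives. Among medians of the lists fixed at the outset, 164 alternative values moved by less than the spread between probe sets allows for a list of that size and 47 by more, against 71 and 13 for the 12 lists chosen after the data were seen. For the lists fixed at the outset, with a floor of 200 the gene list median log2 ratio of cholesterol synthesis was 2.27, and the others that moved were 0.61 for the nucleotide union, -0.78 for B cell, 0.86 for activation receptors, 0.93 for effector genes, -0.85 for interferon, -0.46 for macrophage, 2.32 for mitosis and -1.24 for naive T cell genes. With a floor of 50 they were 0.85 for activation receptors, 2.69 for cholesterol, 0.61 for effector, -1.62 for interferon and 3.60 for mitosis. Quantile normalization gave -0.62 for CD8 and receptor genes, 1.57 for DNA replication, -0.34 for apoptosis, 0.02 for reference genes, -0.021 for ribosomal proteins, 1.33 for glycolysis, 0.36 for the respiratory chain and 0.66 for ribosome biogenesis. Loess gave 1.59 for DNA replication, -0.34 for apoptosis, 0.059 for reference genes, -0.13 for ribosomal proteins, 1.34 for glycolysis and 0.66 for ribosome biogenesis. With the mean over probe sets the gene list median log2 ratio of B cell genes was -1.48, and the others were -0.60 for CD8 and receptor genes, 1.59 for DNA replication, 0.44 for transcription factors, 1.12 for activation receptors, -0.54 for apoptosis, 2.28 for cholesterol, 1.26 for deoxyribonucleotide production, 1.34 for glycolysis, -0.98 for interferon, 2.61 for mitosis, -1.28 for naive T cell genes, 0.091 for nucleoside breakdown and 0.66 for ribosome biogenesis. Without cross-hybridizing probe sets the medians were -0.92 for B cell, 2.40 for cholesterol, 1.61 for glycolysis and 2.93 for mitosis, and without deoxyribonucleotide production the union was at 0.44. Gene ratios were recomputed for the genes of the fixed naming rule and for members past the size rule of the 12 later lists. Of their alternative values, 1997 stayed within the probe set spread of 0.39 and 169 did not. Median, quantile and loess scaling shifted the median log2 ratio of probe sets above 100 on both arrays by -0.01, -0.06 and -0.04. Signal over background limits what can be seen, since 57.3% of probe sets lay under 100 on both arrays. No paired analysis was possible because each group has 1 array.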

Other observations

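The 12 gene lists in this part were chosen after the data had been seen, as were the test on the level of other cells' markers and the immunoglobulin and receptor gamma probe sets. Constitutive proteasome, chaperone and fatty acid synthesis genes were mostly higher on the activated array. The proteasome list had 22 of 24 members higher, with a median log2 ratio of 0.73 (percentile 99.98), as with the core subunit Psmb5 (2.12-fold) and the ATPase Psmc1 (2.31-fold). The immunoproteasome and class I presentation list had none higher and 3 of 11 lower, namely Psmb10 (2.07-fold), Tapbp (1.54-fold) and Tap2 (1.46-fold), with a median of -0.16 (percentile 11.13). Cytosolic and mitochondrial chaperones were higher for 17 of 18 (median 0.89, percentile 100), with the mitochondrial chaperonin Hspd1 4.03-fold higher. Endoplasmic reticulum chaperones and stress genes were higher for 11 of 18 and lower for 2 (median 0.70, percentile 99.8). There the chaperones Hspa5 (2.29-fold) and Pdia6 (2.67-fold) were higher, as were the stress transcription factors Atf3 (at least 4.51-fold), Xbp1 (1.82-fold) and Atf4 (1.53-fold). The stress transcription factor Ddit3 (3.06-fold) and Dnajc3 (1.99-fold, with another probe set of the opposite sign) were lower. Fatty acid synthesis and desaturation genes were higher for 15 of 18 (median 1.03, percentile 100), with the desaturases Scd1 and Scd2 at least 17.9-fold and 6.05-fold higher and the lipid carrier Fabp5 6.20-fold.

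Genes that maintain DNA methylation and heterochromatin were higher for 10 of 15 and lower for 1 (median 0.95, percentile 99.95). Uhrf1, which recruits the maintenance methylase, was 10.8-fold higher and the histone methylase Ezh2 5.91-fold, while Tet1, which oxidises methylated cytosine, was at least 3.40-fold lower. Homing and integrin genes were lower for 9 of 12 and higher for 1, Itgb1 (2.36-fold), with a median of -0.83 (percentile 0.02). The list holds Ccr9 and Itgae, which stand among the 10 lowest ratios above, so its percentile is no separate evidence. Itgb7, the partner of Itgae, was 2.32-fold lower, and Itga4 3.53-fold. Gimap genes, a family of lymphocyte GTPases, were lower for 6 of 8 (median -0.63, percentile 1.79), with Gimap8 at 4329.5 and 1258 (3.44-fold lower). Metallothionein and oxidative stress genes were higher for 6 of 14 and lower for 3 (median 0.36, percentile 91.31), with the thioredoxin gene Txn1 3.94-fold higher and catalase, Cat, 1.58-fold lower.

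B cell and macrophage markers were lower on the activated array, and scaling of the arrays was tested as a cause on the B cell list. Under the deposited, median, quantile and loess scaling the B cell median was at most -1.22, below the limit of -0.41 of matched random lists. The alternative scalings shifted the median log2 ratio of probe sets above 100 on both arrays by only -0.01 to -0.06. They also moved the matched lists, so this shows only that these scalings do not account for the B cell difference. A second list of B cell markers had a median of -0.52 against a limit of -0.45, with 5 lower and 2 higher members, so with members on both sides B cells in the naive pool and other sources cannot be told apart, although the kappa chain probe sets above (-5.21 to -4.45) went with B-lineage cells. The purification method is not given in the sources used here. For the marker lists as sets, activation itself, the difference between the groups, stays open and was not tested. Some single genes of other blood cells were high on the naive array. These were alpha-globin (8254 and 25.4), Jchain (1768 and 45.25) and the kappa chain, at 4589 and 124.3 by 1 shared probe set. For these genes the values go with RNA of other blood cells in the naive pool and argue against activation of the T cells alone.

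Interferon response genes were lower on the activated array, and the highest median under any of the 4 scalings was -1.12, below the limit of -0.38. The alternative scalings changed little and moved the matched lists too. The result therefore shows only that these scalings do not account for the interferon difference. On the naive array 6 of 77 markers of other cell types exceeded 722, the median naive value of the lower interferon genes, but levels of different probe sets are not comparable and this count decides nothing. Interferon-responding cells of other types in the naive pool and a source in the T cells therefore cannot be told apart. Activation, the difference between the groups of the design, stays open as well and was not tested apart from these.

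Genes of memory-phenotype and innate-like CD8 T cells were lower for 13 of 18 members and higher for 2, in a list chosen in part for genes already seen to be lower, since 12 of the 18 also stand in lists fixed at the outset. Ccl5 was 7.24-fold lower, Cxcr6 4.60-fold, Gzma 4.27-fold and Eomes 3.37-fold, and the median was at most -0.94 under each of the 4 scalings. That shows only that these scalings do not account for the difference. Given how the list was chosen, the median is no evidence for the pattern. A gamma delta and innate-like T cell list, without the already seen Il18r1, had a median of -0.44 over 7 members against a limit of -0.55 and a spread of 0.18, so such cells in the naive pool cannot be told apart from a difference within the CD8 T cells. T cell receptor gamma probe sets went with such cells, namely Trgv1 (859 and 175), 1 shared by Trgv2 and Trgv4 (727 and 150.1) and 2 of Trgv4 (423 and 85.0, and 303 and 41.6), although CD8 T cells can also carry gamma chain transcripts. With Il18r1 the list had 4 of 8 lower (median -0.52, percentile 2.12), among them Rora (at least 2.94-fold) and 5830411N06Rik (at least 5.03-fold), and Cd163l1, chosen after its value was seen, was at 1672 and 55.05.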
